A study of Sus scrofa with 8 samples.

How the data were processed

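The 8 samples were IP and input libraries of muscle from 2 Landrace and 2 Jinhua males, aged 180 days. Per the labels' protocols, RNA was extracted with TRIzol, mRNA was purified on Dynabeads, IP samples were sonicated and precipitated with an m6A antibody from Synaptic Systems, and libraries were made with a stranded TruSeq kit. The submitters' processing notes name TopHat2 2.0.14 and the builds Sscrofa10.2 and susScr3. The peak caller, its threshold and the annotation release are not given in the sources used here. The authors deposited 1 peak list per animal, so animals were not pooled. Per the file headers, a row holds a gene identifier, a symbol, 1 transcript, the number of peaks, and the start, end and annotated part of the transcript for each peak. Positions are 1-based on the transcript, not on the genome, and no genome coordinates are printed. No list holds fold enrichment, p-values or counts. Depth per sample is therefore unknown, and a longer list may reflect depth or IP efficiency. Animals were grouped by the breed in the labels, and the labels describe 2 separate males per breed.

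The lists of Jinhua 2 and Landrace 1 give positions for at most 4 peaks per gene and the part of the transcript for at most 3. In these lists 320 and 229 peaks have no position. To treat the lists alike, the 228 genes with more than 4 peaks in any list were left out of results by position, leaving 5422, and location was taken from the 5132 genes with 3 or fewer peaks in each list. Counts of genes and peaks use all rows. In Jinhua 1 and Landrace 2, 11 entries beyond the stated number of peaks were not used. Symbols came from the lists, which gave none for 1180 identifiers. The gene name table named 520 of these and 660 stayed unnamed. The table held 4045 of the 5650 identifiers, and its symbol differed from the list's in 208 of 3525 genes that had both, where the list's symbol was kept. Between any 2 lists 1.79% to 4.92% of peaks had the same start and end, so no list was a copy of another.

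A gene was called in an animal with 1 or more peaks. Peaks that overlapped or directly adjoined on a transcript were merged into regions over the 4 lists. Jinhua-only and Landrace-only features were those called in both animals of one breed and in neither of the other, and were set beside both splits that mix the breeds. The product ratio is the product of the 2 same-breed counts over the product of the 2 counts of a mixed split, as the geometric mean over both mixed splits, with a 95% interval from the counts. That interval treats features as independent, although several regions can lie in 1 gene. Overlap was the Jaccard index in bases over the 6 pairs of animals. Breed means were compared by exact permutation. Each of 17 gene lists, fixed before the data were examined, was tested by Fisher's exact test against all other called genes, once per breed, with Benjamini-Hochberg adjustment over the 34 tests. Genes are not independent replicates, so these p-values describe the 4 animals and not the breeds. Another 14 gene families were put together after the data had been seen and tested the same way, over 28 tests. Location shares have 95% Wilson intervals.

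The text names MTCH2 and the called members of the m6A machinery list, the 10 leading genes of each breed-specific set and of the genes called in all 4 animals, and, for each list, up to 4 breed-specific members and up to 2 called in all 4. The ranking was planned on fold enrichment. As the lists hold none, genes were ranked by the mean number of peaks where called, then by the mean bases covered, then by symbol. Genes without a symbol were skipped, and some genes that the rule names are not reported here. Regions in ETFDH, HADH, CRAT and MYH7, and the members of the added gene families, were named after their values were seen. Stricter enrichment thresholds, equal list lengths by p-value and the sequence under peaks were planned and could not be computed from these lists. The alternatives tried were leaving out each animal, a larger minimum overlap, set relative to the shorter peak, joining nearby peaks, another overlap measure, another background, and others added after the data had been seen.

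The steps were tested on simulated calls for 9000 genes in 4 animals with unequal list lengths modelled on those observed. With no breed effect the product ratio averaged 1.00 over 50 draws, between 0.765 and 1.32. These calls were drawn from a gene term and an animal term, under which the ratio is 1.00 apart from sampling. They held no batch and no expression shared within a breed. The draws thus check the computation and set no range for real data. With the genes planted below the mean ratio was 1.48. For the comparison of breed-specific genes, 200 genes were planted with a chance of a call of 80% in Jinhua and 5% in Landrace, and 57.7% of them came out as Jinhua-only, where 57.8% were due. A list of 30 planted genes passed in 100% of draws and a random list in 0%. Every member of that planted list had the breed difference in call chance. In the real fatty acid oxidation list, by contrast, 4 of 23 called members were Jinhua-only. The draws therefore set no power for lists with few breed-specific members. Power under the adjustment used for the real lists was not tested. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.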

Results

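Messenger RNA methylated at the N6 position of adenosine (m6A) was profiled in muscle of 2 Landrace pigs, a Danish breed, and 2 Jinhua pigs, a Chinese breed with more intramuscular fat. All 4 animals were males aged 180 days. Each animal gave an immunoprecipitated (IP) library, enriched with an antibody against m6A, and an input library, so the 8 samples form 4 groups of 2. The study asked what m6A does in the deposition of fat within muscle. The deposited data are 4 lists of m6A peaks, 1 per animal, with each peak placed on an Ensembl transcript. The lists give no read counts, enrichment or p-values, so the depth of each library is unknown. A gene could be compared between animals only by whether a peak was called, and a gene without a call may have been weakly expressed rather than unmethylated. With 2 animals per breed, no exact two-sided test of the breeds can go below p = 0.333.

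The series title names MTCH2, a protein of the outer mitochondrial membrane, as a transcript whose translation m6A enhances. MTCH2 (ENSSSCG00000013232) carried 1 peak in both Jinhua animals and in Landrace 1, and none in the list of Landrace 2. The 3 peaks lay at the same place, the first bases of transcript ENSSSCT00000014452. They covered bases 1 to 117 in Jinhua 1, 1 to 119 in Jinhua 2 and 1 to 120 in Landrace 1, and were annotated as coding sequence. The call therefore did not separate the breeds. The peak began at base 1, the 5' end of the transcript model, and no other MTCH2 peak was listed in any animal. Among the writers, erasers and readers of m6A, 9 of 24 listed symbols, 23 of them annotated, carried a peak in at least 1 animal. The demethylase ALKBH5, the reader YTHDF2, the RNA-binding protein HNRNPC and the translation initiation factor EIF3A were called in all 4. ALKBH5 had 2 peaks in each Jinhua animal and 3 in each Landrace animal. The additional peak lay in the 3' UTR, at bases 2225 to 2379 of ENSSSCT00000024532 in Landrace 1 and 2279 to 2433 in Landrace 2. EIF3A and YTHDF2 ran the other way, each with 2 peaks in Jinhua 1, 3 in Jinhua 2 and 1 in each Landrace animal. Each held 1 Jinhua-only region in the coding sequence, at bases 3821 to 3970 of ENSSSCT00000011680 for EIF3A and 1741 to 1885 of ENSSSCT00000027438 for YTHDF2. The list thus had 2 Jinhua-only regions and 1 Landrace-only region. The writer component ZC3H13 had 4 peaks in Jinhua 2, 2 in Landrace 1 and 3 in Landrace 2, and none in Jinhua 1. RBM15 had 2 peaks in Jinhua 1 and 1 in Landrace 2. METTL3, the catalytic writer subunit, and its partner WTAP had 1 peak each in Jinhua 2 alone, and RBM15B had 1 in Landrace 1 alone. No member of this list was called in both animals of one breed and in neither of the other. Over all called genes this held for 428 of 5650 (7.58%), so 9 called members are too few to differ visibly from that share. YTHDF1, the reader named in the title, was not found by symbol in any of the 4 lists.

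Most of the called contractile and calcium-handling transcripts carried a peak in every animal. A peak was called in 5650 genes in at least 1 animal and in 2474 genes (43.8%) in all 4, while 1375 were called in 1 animal, 898 in 2 and 903 in 3. The genes with most peaks were long transcripts. DST, which encodes a cytoskeletal linker, had 13 and 19 peaks in the Jinhua animals and 16 in each Landrace animal. RYR1, the calcium release channel of the sarcoplasmic reticulum, had 11 and 14 against 12 and 12. The splicing factor SRRM2 had 11 in each Jinhua animal and 10 in each Landrace animal. Nebulin (NEB), listed under 2 gene identifiers, had 10, 12, 9 and 8 peaks under the first, in the order Jinhua 1, Jinhua 2, Landrace 1 and Landrace 2, and 8, 9, 9 and 8 under the other. The histone methyltransferase gene KMT2D, PRRC2B, PRRC2A, AHNAK and SSH2 completed this group, with means of 9.25, 9, 8.25, 8.25 and 8 peaks. Of 45 called sarcomere genes, counted by identifier, 40 were called in all 4 animals. For calcium handling this held for 23 of 25, among them RYR1 and the calcium channel subunit CACNA1S with a mean of 7.75 peaks. For mitochondrial carriers and dynamics it held for 15 of 18, including PINK1 and MFN2. Of the regulators of muscle formation and wasting, 16 of 26 were called in all 4, including MEF2D and FOXO1. Among 20 listed fibroblast and fibro-adipogenic markers 19 were called and 13 were shared by all 4, including the collagens COL6A3 and COL3A1. The endothelial and vascular list had 10 of 13 in all 4, including PECAM1 and ENG.

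**Figure D1:**
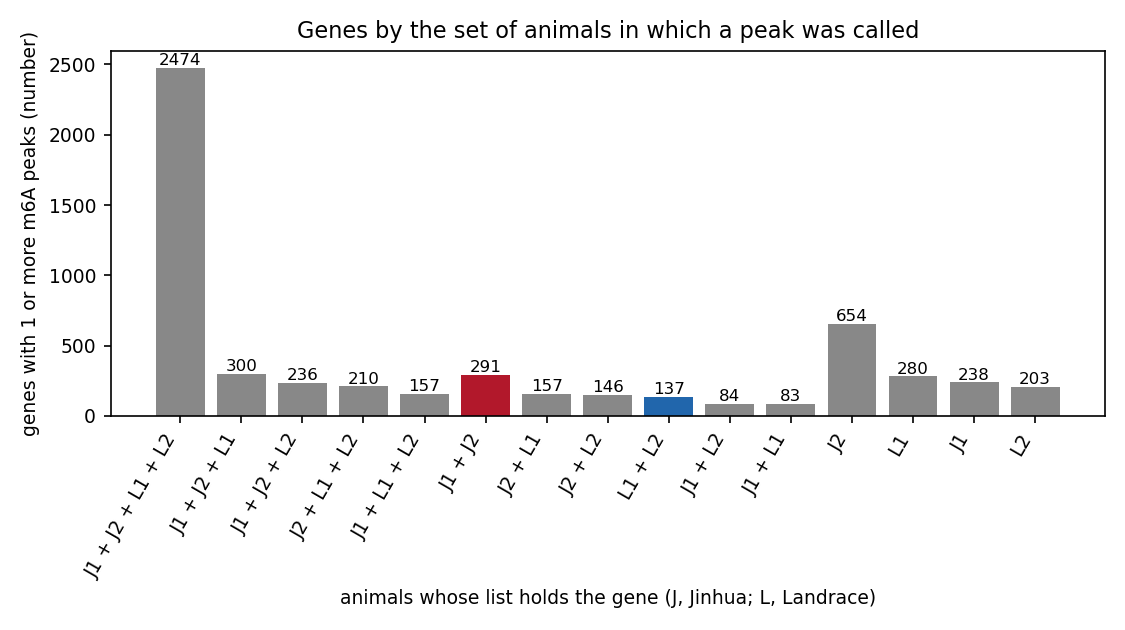
Number of genes with 1 or more m6A peaks (vertical axis) for each set of animals whose list holds the gene (horizontal axis), with J for Jinhua and L for Landrace. 2474 genes were called in all 4 animals, 291 in both Jinhua animals alone (red) and 137 in both Landrace animals alone (blue), in lists of unequal length (3647 to 4468 genes).

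Genes called in both animals of one breed and in neither of the other numbered 291 for Jinhua and 137 for Landrace. In the same way 83 genes were called only in Jinhua 1 and Landrace 1, and 84 only in Jinhua 1 and Landrace 2. For Jinhua 2 the counts were 157 with Landrace 1 and 146 with Landrace 2, both above the Landrace-only count. With every list thinned at random to 3647 genes, the shortest length, means over 100 draws were 233 Jinhua-only and 201 Landrace-only. Thinning drops genes without regard to the strength of a call, which the lists do not give. Some genes shared by the breeds thereby become breed-specific by construction. The Jinhua-only genes with most peaks included YAP1, the effector of the Hippo pathway, with 2 and 3 peaks, and PPP1R3A, the muscle subunit that directs protein phosphatase 1 to glycogen, also with 2 and 3. KIAA1919 had 3 in each Jinhua animal, PDCD6IP 3 and 2, and ZDHHC9 2 and 3. The histone methyltransferase gene SETD1B had 2 and 3, and DNAJC21, the kinase gene HIPK3, AP2B1 and VIT had 2 in each. The Landrace-only genes with most peaks were FNDC1, with 5 in Landrace 1 and 4 in Landrace 2, and SAMD4B, with 4 and 2. KCNQ5, which encodes a potassium channel, had 3 and 2, and the cadherin DCHS1 had 4 and 1. TMEM132A, CSRNP1 and the microtubule-associated gene MAP1B had 3 and 1, and RUSC1, ASAP2 and SLCO3A1 had 2 in each. No ASAP2 peak overlapped between the 2 Landrace animals, and for RUSC1 only the first peak did. Of the Jinhua-only genes 209 had a single peak in both animals. Peaks of both animals overlapped or adjoined in 255 of the 291 Jinhua-only genes (87.6%) and in 121 of the 136 Landrace-only genes with complete positions (89.0%).

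The breed split parted more genes than either split that mixed the breeds. It gave 428 genes, against 229 for Jinhua 1 and Landrace 1 set against the others and 241 for Jinhua 1 and Landrace 2 set against the others. The product of the same-breed counts exceeded the products of the mixed counts by a ratio of 3.15 (95% counting interval 2.39 to 4.16). This ratio does not depend on list length where each gene's odds of a call in an animal multiply a gene term and an animal term. With only 3 splits of 4 animals this ordering has no test that could reach 0.05, and the interval describes these 4 animals. By position, overlapping or adjoining peaks were merged into 9414 regions in 5422 genes. Of these regions 2552 (27.1%) held a peak in all 4 animals and 3704 (39.3%) in 1. There were 526 Jinhua-only and 318 Landrace-only regions, with a ratio of 3.07 (2.54 to 3.71). Within genes called in all 4 animals, 171 regions were Jinhua-only and 140 Landrace-only.

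More genes of fatty acid oxidation carried a peak in each Jinhua list than in each Landrace list, an ordering whose exact p cannot go below 0.333 in this design. Of 26 genes in the list, 21 carried a peak in each Jinhua animal, 16 in Landrace 1 and 15 in Landrace 2. The same ordering held for all called genes, 3863 and 4468 in the Jinhua lists against 3798 and 3647, and for 5 of the 17 lists, this one included. The others of the 5 were adipogenesis regulators, lipid droplet and lipolysis, sarcomere, and insulin, IGF and AMPK signalling. The immune list ran the other way (3 and 4 against 5 and 5), and 11 lists had neither order. The 4 called in both Jinhua animals and in neither Landrace animal were ACADM, the medium-chain acyl-CoA dehydrogenase, ACAA2, the mitochondrial thiolase, and ETFA and ETFB, which together form the electron transfer flavoprotein. ACADM had peaks at bases 1366 to 1531 of ENSSSCT00000004179 in Jinhua 1 and 1403 to 1558 in Jinhua 2, in the coding sequence. The ACAA2 peaks lay in the 3' UTR, at bases 1771 to 1926 of ENSSSCT00000004982 in Jinhua 1 and 1735 to 1890 in Jinhua 2. UCP3 and ACADS were called in all 4 animals. The 4 Jinhua-only genes were 17.4% of the 23 called members, against 5.10% of the 5627 other called genes (odds ratio 3.92). Fisher's exact test, two-sided, gave p = 0.0281 before and 0.956 after Benjamini-Hochberg adjustment over 34 list tests, so the list did not pass. Without Jinhua 1 the odds ratio was 1.39, without Landrace 2 it was 2.08, without Jinhua 2 it was 2.5 and without Landrace 1 it was 2.87. With 1 animal left out a single list decides for its breed, so breed-specific genes become more numerous by construction. Without Jinhua 1 the Jinhua-only genes rose from 291 to 945, and the list members among them from 4 to 5. These values therefore do not show which library the odds ratio rests on. By position the list held 6 Jinhua-only regions, those of the 4 genes plus ETFDH and HADH, and 1 Landrace-only region, in CRAT.

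Other genes of lipid handling mostly did not part the breeds, as was true of called genes at large, where 428 of 5650 (7.58%) did. Of fatty acid synthesis and uptake, 23 of 37 genes were called and 13 were shared by all 4 animals, among them SCD, the stearoyl-CoA desaturase, with 3, 5, 6 and 5 peaks, and LPIN1 with 2, 6, 4 and 4. CD36, the fatty acid transporter, was the single breed-specific member. It had 2 peaks in Jinhua 1 and 1 in Jinhua 2, overlapping in the coding sequence at bases 121 to 240 and 91 to 190 of ENSSSCT00000034552. Of lipid droplet and lipolysis genes, 9 of 14 were called in all 4, including MGLL and BSCL2, and none was breed-specific. Of adipogenesis regulators, 10 of 25 were called in all 4, including FGFR1, and again none was breed-specific. Among 6 called adipocyte markers LIPE and CIDEC were called in all 4, and THRSP, which promotes lipogenesis, was Landrace-only, at bases 221 to 364 of ENSSSCT00000016240 in Landrace 1 and 281 to 380 in Landrace 2.

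In the muscle and signalling lists the breed-specific members were few, as they were over all called genes, 428 of 5650 (7.58%). Jinhua-only genes made up 4.44% of called sarcomere genes, against 5.16% of other called genes. For insulin, IGF and AMPK signalling the shares were 11.5% and 5.12%. Of the sarcomere list TNNT1, the slow skeletal troponin T, and PDLIM5 were Jinhua-only. The TNNT1 peak covered bases 1 to 167 of ENSSSCT00000023274 in Jinhua 1 and 12 to 168 in Jinhua 2, whereas the PDLIM5 peaks of the 2 animals did not overlap. Of 27 called genes of glycogen and glycolysis 18 were shared by all 4, including the glycogen synthase GYS1 and PHKA1, and PPP1R3A was Jinhua-only. Of 26 called genes of insulin, IGF and AMPK signalling 15 were shared, including MTOR and IRS1. The insulin receptor INSR and the S6 kinase RPS6KB1 were among the Jinhua-only genes, and the list did not pass (Fisher's exact p = 0.147, adjusted p = 1). Of 21 called genes of Wnt and TGF-beta signalling 9 were shared, including FZD4 and LTBP3, and the inhibitory SMAD7 was Landrace-only, at bases 276 to 461 of ENSSSCT00000004979 in Landrace 1 and 279 to 453 in Landrace 2. The vascular list held 1 Landrace-only gene, the smooth muscle myosin MYH11. The immune list, with 6 called genes, also held 1, the monocyte marker CD14, beside C1QC and CSF1R in all 4 animals. Of nerve, satellite cell and blood markers, haemoglobin HBB was called in all 4 and no gene was breed-specific. None of the 34 tests passed an adjusted p of 0.05, and the fatty acid oxidation list was the single test with an unadjusted p below it.

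**Figure D2:**
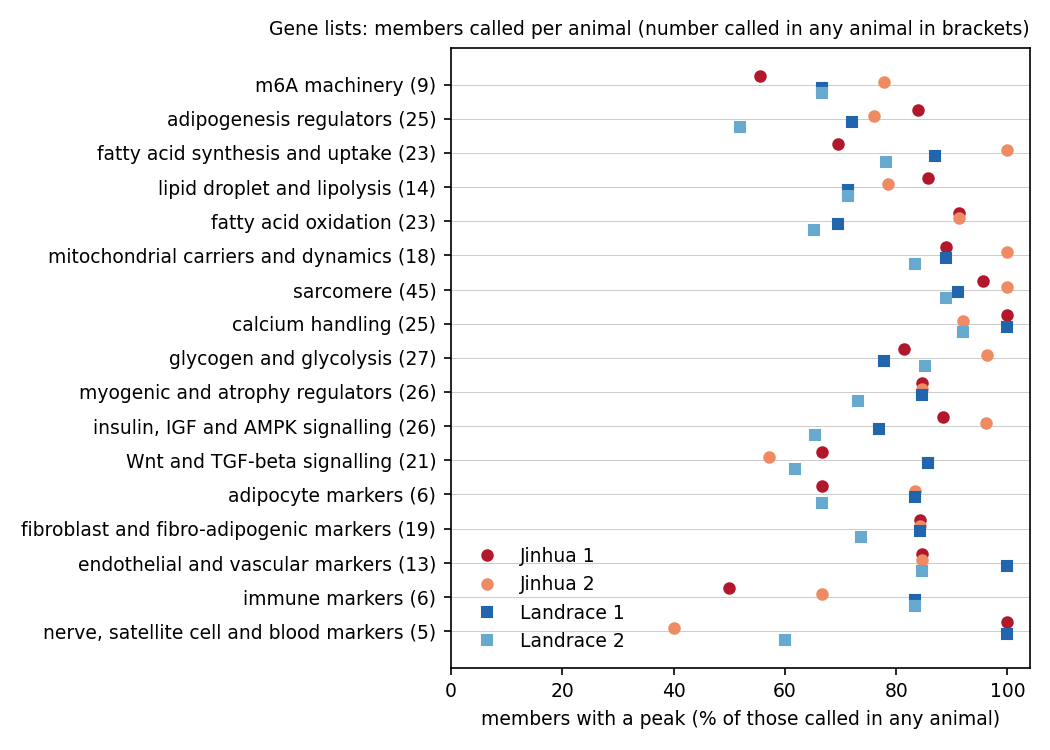
Share of each gene list's called members (horizontal axis, %) that carried a peak in each animal (circles, Jinhua; squares, Landrace), with the number of members called in any animal in brackets. For fatty acid oxidation 21 of 23 members were called in each Jinhua animal, 16 in Landrace 1 and 15 in Landrace 2.

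The number of peaks did not separate the breeds beyond the spread between animals. Jinhua 1 had 6433 peaks in 3863 genes, Jinhua 2 had 7733 in 4468, Landrace 1 had 6471 in 3798 and Landrace 2 had 6176 in 3647. The breed means were 7083 ± 919 peaks in Jinhua and 6324 ± 209 in Landrace (SD, n = 2 each, exact permutation p = 0.667, two-sided). The difference of 759.5 rested on Jinhua 2 and was 109.5 without it. Without Jinhua 1 it was 1410 peaks, and in genes with complete positions it was 708.5 over all peaks and 456.5 over peaks of 150 bases or more. For genes the means were 4166 ± 428 and 3723 ± 107 (SD, n = 2 each, exact permutation p = 0.333). Median peak width was 159, 157, 156 and 157 bases, in the same order of animals, and peaks per gene were 1.67, 1.73, 1.70 and 1.69.

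Peaks lay mostly in coding sequence in every animal. Among genes with 3 or fewer peaks in each list, coding sequence held 67.3% of peaks in Jinhua 1 (95% Wilson interval 66.0 to 68.7), 70.6% in Jinhua 2 (69.4 to 71.7), 69.8% in Landrace 1 (68.5 to 71.1) and 69.8% in Landrace 2 (68.5 to 71.2). The 3' UTR held 25.2% (24.0 to 26.5), 21.4% (20.3 to 22.5), 21.0% (19.9 to 22.2) and 22.4% (21.2 to 23.7). The 5' UTR held 6.89%, 7.19%, 8.45% and 6.96%. The breed means for the 3' UTR were 23.3% ± 2.73 in Jinhua and 21.7% ± 0.999 in Landrace (SD, n = 2 each, exact permutation p = 0.667). Without Jinhua 1 the difference of 1.58 percentage points turned to -0.355. The difference in coding sequence, -0.872 points, also turned without Jinhua 1, to 0.731, and that in the 5' UTR, -0.667 points, turned without Landrace 1, to 0.0777. The intervals cover counting error of peaks only. The shares rest on the annotated parts given in the lists and were not set against the length of each part.

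**Figure D3:**
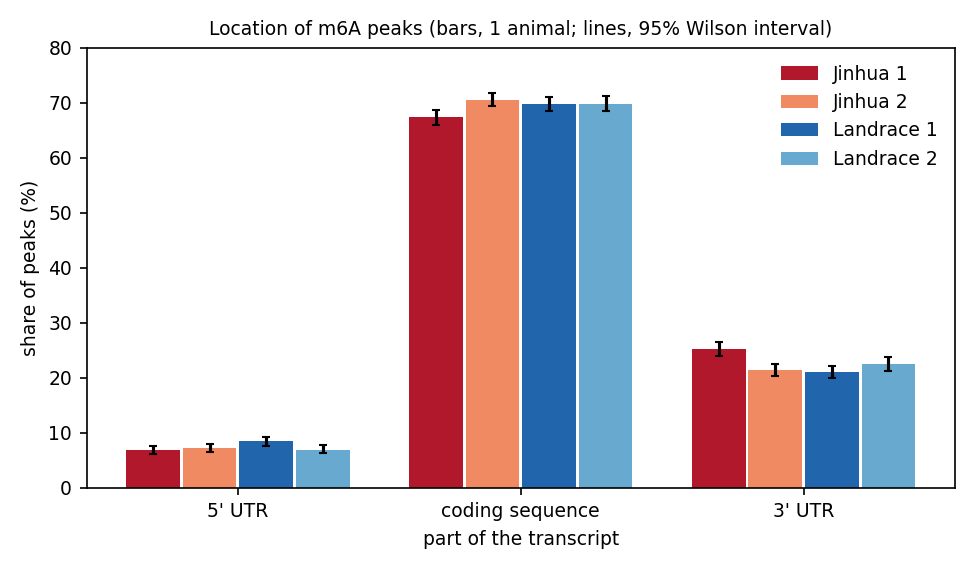
Share of peaks (vertical axis, %) in each part of the transcript (horizontal axis) per animal, with 95% Wilson intervals as lines, for genes with 3 or fewer peaks in each list. Coding sequence held between 67.3% and 70.6% of peaks in the 4 animals.

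Animals of one breed shared slightly more bases in peaks than animals of different breeds on average. The Jaccard index, the bases in peaks of both animals over the bases in peaks of either, was 0.445 for the Jinhua pair and 0.463 for the Landrace pair. Between breeds it was 0.426 and 0.446 for Jinhua 1 with Landrace 1 and Landrace 2, and 0.379 and 0.386 for Jinhua 2 with them. The within-breed mean of 0.454 exceeded the between-breed mean of 0.409 by 0.0448, the highest of the 3 splits (exact permutation p = 0.333, one-sided, the smallest this design allows). Jinhua 1 with Landrace 2 overlapped as much as the Jinhua pair. Unequal list lengths can lower this index, and no correction for length was made. Both lowest values belonged to Jinhua 2, the longest list, which is also part of the Jinhua pair. Without Jinhua 1 the difference was 0.0808, and without Jinhua 2 it was 0.0269. Without Landrace 1 it was 0.0292.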

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

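Entries beyond the stated number of peaks stood out as data outside the main measurement. There were 11 in all, of which 1 belonged to DST in Jinhua 1, 8 to DST in Landrace 2 and 2 to RYR1 in Landrace 2. Of these, 5 overlapped a listed peak of the same animal and 7 overlapped a listed peak of any animal. Whether they are peaks that were dropped or remains of an earlier version of the list was not tested.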

How the results depend on the processing

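Alternatives that join nearby peaks or ask for a larger overlap were chosen before the data were examined. Those that drop peaks at base 1, keep only wide peaks, keep only genes called in all 4 animals, use genes for bases, or thin the lists were chosen after. Leaving out 1 animal lets the animal left decide alone, so counts rise by construction: to 900 to 2123 Jinhua-only and 612 to 1125 Landrace-only regions, and to 527 to 945 Jinhua-only and 294 to 417 Landrace-only genes. Location differences ran from -1.41 to 0.0777 percentage points for the 5' UTR, -2.47 to 0.731 for coding sequence and -0.355 to 3.51 for the 3' UTR, with the turns named above, and the cause was not tested. In genes with complete positions Jinhua animals had 708.5 more peaks on average, and 456.5 more with only peaks of 150 bases or more. That width limit left 349 Jinhua-only regions, with fewer peaks entering by construction. Jinhua-only regions numbered 171, beside 140 Landrace-only, in genes called in all 4 animals, where fewer regions enter by construction. The MTCH2 call fell from 3 animals to 0 without peaks that start at base 1, by construction. Random thinning of every list to 3647 genes gave means of 233 Jinhua-only and 201 Landrace-only genes and a product ratio of 2.52. As genes are dropped without regard to the strength of a call, part of this shift arises by construction. Over the alternatives run, the product ratio was between 2.52 and 3.23 for genes and between 2.93 and 3.37 for regions. The difference in overlap between breeds stayed above 0 in all alternatives run. With the replicate block, which compares only animals of different number between breeds, it was 0.0417. Between-breed pairs of the same number had a mean index of 0.406 and those of different number 0.412. These pairs are too few to tell whether the number marks a shared preparation or run. No gene list passed under any alternative run, and the odds ratio of fatty acid oxidation was 1.39 to 4.65. Alternatives that need enrichment or p-values, the sequence under peaks, and a filter for exonic peaks, which would remove none, were not run. Depth is unknown, so absent calls have no limit of detection.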

Other observations

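The gene families described next were put together after the data had been seen, and none passed the adjustment over 28 tests. Of 69 cytosolic ribosomal protein genes 44 carried a peak in at least 1 animal, with 33, 36, 34 and 33 called in Jinhua 1, Jinhua 2, Landrace 1 and Landrace 2. RPS26 and RPS28 were Landrace-only. Of 67 mitochondrial ribosome genes 43 were called, with 32 and 34 in the Jinhua animals and 18 and 27 in the Landrace animals, and MRPL30, MRPL45 and MRPS18A were Jinhua-only. For the proteasome the counts were 28 and 27 against 24 and 21, with PSMA4, PSMA5 and PSMD1 Jinhua-only. For respiratory complex I they were 25 and 24 against 23 and 22, with NDUFA1, NDUFA9 and NDUFB1 Jinhua-only and NDUFV3 Landrace-only. Of the mitochondrial import genes TIMM21 and TIMM8A were Jinhua-only, and TOMM6 and TOMM7 were Landrace-only (each 2 of 13 called members, Fisher's exact p = 0.142 for the Jinhua side and 0.0382 for the Landrace side, adjusted p = 0.788 for both). Zinc finger genes were called rarely, 46 of 269 in any animal (17.1%), against 30.6% of all annotated symbols, a comparison that was not tested. Of solute carriers 69 of 347 were called, with 5 Jinhua-only and 2 Landrace-only. Of collagens 17 of 40 were called and 13 were in all 4 animals. Kelch-like genes (9 of 36), F-box genes (20 of 59), USP deubiquitinases (21 of 47) and ZBTB genes (12 of 40) completed the families, with adjusted p of 0.788 or more.

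Peaks that began at base 1 of a transcript made up 5.81%, 5.26%, 7.02% and 5.80% of placed peaks, in the order Jinhua 1, Jinhua 2, Landrace 1 and Landrace 2. Of those with an annotated part, 81.0%, 82.2%, 79.2% and 79.1% were given as coding sequence, as for MTCH2, TNNT1 in Jinhua 1, and HBB in all 4 animals. MYH7, the slow myosin heavy chain, called in all 4 animals, held 3 Jinhua-only regions and 1 Landrace-only region.

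Of the tests below, the one on peaks at base 1 was set out before its result was seen and the others after. The first pattern is the greater number of Jinhua-only than Landrace-only genes, a ratio of 2.12 (95% counting interval 1.73 to 2.60). Genes called in exactly 3 animals give an expected ratio of 2.15 for lists of these lengths, and genes called in 1 animal give 2.74. The observed ratio was 0.989 times the first of these (0.707 to 1.38), which is in line with the longer Jinhua lists as its source. A larger number of methylated transcripts in Jinhua, the biological reading, was not tested, since a longer list and a wider methylation cannot be separated without depth.

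The second pattern is that the breed split parted more genes than either mixed split, with a product ratio of 3.15. It did not hold for every pair of animals. The Landrace pair alone had 137 genes, against 83, 84, 157 and 146 for the mixed pairs. Genes called or missed as a whole are not the sole source of this excess. Within genes called in all 4 animals the product ratio of regions was 3.37 (2.47 to 4.60). For the 533 breed-specific regions in the other genes, calling or missing of whole genes stays open as a source. Several regions can lie in 1 gene, so intervals over regions may be too narrow. Without peaks that start at base 1 the ratio was 3.14 (2.58 to 3.81), so those peaks are not the sole source of the excess. They were only 5.26% to 7.02% of placed peaks per animal. Peaks that start a few bases further in and peaks at the 3' edge were kept, so the transcript edge as a whole was not tested. Libraries of one breed prepared or sequenced together cannot be told apart from breed, because 0 of the samples' labels name a batch. The breed split was 1 of 3 and gave 428 genes against 241 for the highest other, and 3 splits are too few for a share under 0.05. A difference between the breeds in methylation, or in expression that moves a peak across the caller's threshold, stays open.

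The third pattern is the calling of fatty acid oxidation genes in Jinhua. For longer Jinhua peak lists as the source, the lists of Jinhua 1 and Landrace 1, with 3863 and 3798 genes, were compared. Here 5 members were called in Jinhua 1 alone and 0 in Landrace 1 alone (exact sign test p = 0.0625, two-sided, the smallest that 5 members can give), so this test could not exclude list length; Jinhua 2 against Landrace 1 also gave 5 to 0, and each Jinhua animal against Landrace 2 gave 7 to 1 (exact p = 0.0703). More slow, oxidative fibres in the Jinhua samples stays open as a hypothesis: slow fibre genes were called 5 and 6 times in the Jinhua lists and 3 times in each Landrace list, so the lower Jinhua list exceeded the higher Landrace list by 2. The 10 called fast fibre genes were called in every animal, so they could show no shift and give no contrast, and the slow fibre list, with 7 called genes, was made after TNNT1 had been seen.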
